A study of Homo sapiens with 6 samples.

How the data were processed

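RNA was measured in 6 libraries of EndoC-βH1 cells (EndoCBH1 in the labels), a human beta cell line derived from fetal pancreas. In 3 libraries the cells had received siRNA against MNX1 (siMNX1), and in the other 3 a non-targeting siRNA (siNT). Groups and replicate numbers were taken from the sample titles. The labels do not say whether the numbers mark separate cultures or, for siMNX1, separate siRNA sequences, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with a column kit and libraries were made from 5 ng of total RNA with the Ovation Solo kit, with ribosomal RNA removed by AnyDeplete. The labels' molecule field names polyA RNA, and the protocol describes removal of ribosomal RNA.

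The authors deposited one table of normalized counts (a signal per gene, never negative, with decimals) for 16792 genes. Per the submitters' processing notes the genome build was GRCh38 and the tools were STAR 2.7.6a, RSEM 1.3.1, R 3.6.3, DESeq2 1.26.0 and DESeq, with no role or order stated. The annotation release, the filter that left these genes and the handling of strand are not given in the sources used here. Deposited totals were 18406479, 18600819 and 18520644 in siNT replicates 1 to 3 and 18436560, 18704645 and 18537249 in siMNX1 replicates 1 to 3. These totals follow the normalization and are not depths. Low values of a library clustered near multiples of one step, but only 25.8% to 47.4% of values under 10 lay within 0.02 reads of a whole multiple, so whole reads could not be recovered and no count model was fitted. The steps gave rough estimates of the reads on the listed genes, from 15300000 in siMNX1 replicate 1 to 21900000 in siNT replicate 3. No counting interval was computed, because the reads behind each value are unknown.

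Values were analysed as log2(value + 1). A linear model of group was fitted with limma 3.58.1 (R 4.3.3) with a variance trend on expression, and p-values were adjusted by Benjamini-Hochberg over all genes tested. The threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. A minimum mean of 5 over the 6 libraries removed 0 genes, since the lowest mean was 6.57. The 26 gene lists, the limma comparison of the groups and the tests of the lists were fixed before the data were examined, as were most of the other settings tried. Some further tests, named where they are given, were chosen after. List members missing from the deposited genes could not be assessed, so list counts are of measured members. Each list was compared with all other genes by camera (preset inter-gene correlation 0.01), again with an estimated correlation, and by fry, which asks whether a list's own genes move one way on balance and, in its mixed form, whether they change in either direction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation and plots.

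Symbols were present for 14738 genes. Of the other 2054 genes, 417 were named from a gene table by their identifiers, and 1637 had no symbol. Positions came from GENCODE 29 on GRCh38 and were found for 16593 genes. Genes named in the text followed a rule. MNX1, PERCC1, SST, INS, IAPP, GCG and MNX1-AS1 were always named, and GCG was not analysed here. The rule added the 10 largest changes in each direction among genes past the threshold with a symbol, a mean of at least 50 and no overlap between groups. It added the 5 smallest adjusted p in each direction. In each list it took up to 4 members past the threshold or, where none passed, the 2 most abundant. Genes named outside this rule are stated to be so, and some genes that the rule took are not reported here.

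Libraries were compared before they were averaged. No value was identical between any pair of libraries, and within groups the squared differences were 4.38 to 7.16 times a rough estimate of counting noise, so no pair looked like repeat deposits of 1 library. This does not show that the libraries are independent. The procedure was tested on simulated data for siMNX1 against siNT with all 16792 genes and 200 changed genes. The simulated spread was drawn from the variance model that limma fitted to these data, with genes independent of each other. The procedure was thus tested under its own assumptions, without correlation between genes. It recovered 66% of genes changed 1.5-fold, 82% changed 2-fold, 94% changed 4-fold and 100% changed 8-fold. Of all simulated calls, 7.57% were false, above the nominal rate of the threshold, and 0 genes were called when none had been changed. The alternatives were other pseudocounts, a stricter filter, other scalings, a robust variance model, a replicate block, each library left out in turn, a lower fold threshold and an estimated correlation. Scaling to equal totals of non-mitochondrial genes, a correction for transcript length and GC content, and leaving out both libraries of highest mitochondrial share were chosen after seeing the data.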

Results

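RNA levels were compared between EndoC-βH1 human beta cells given siRNA against MNX1 and cells given a non-targeting siRNA, with 3 libraries in each group. The study asked whether the homeobox transcription factor MNX1 holds down somatostatin in beta cells by repressing PERCC1. Levels are given as the authors' normalized counts, as mean ± SD with n = 3 per group. Deposited totals ran from 18406479 to 18704645 per library, which follows the normalization. Mitochondrial transcripts made up 6.10% ± 0.707 of the siNT totals and 5.83% ± 0.572 of the siMNX1 totals (exact two-sided permutation test, p = 0.7, where 0.1 is the smallest p that 3 against 3 libraries allow). The first principal component held 39.2% of the variance and separated the groups. On the second component, with 18.9% of the variance, siMNX1 replicate 2 stood apart at 17.9, while the other libraries lay between -9.59 and 6.78.

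The targeted transcript itself was only slightly lower in the siMNX1 libraries. MNX1 (chromosome 7, 156994051 to 157010651, minus strand, GRCh38) had 2039, 2033 and 1988 normalized counts in siNT replicates 1 to 3 and 1885, 1708 and 1751 in siMNX1 replicates 1 to 3. Its log2 fold change was -0.18 (95% interval -0.31 to -0.06), lower in 3 of 3 siMNX1 libraries than in any siNT library, and did not pass the threshold (limma, adjusted p = 0.116). MNX1-AS1, a transcript from the opposite strand that starts next to MNX1, had 184 ± 3.93 in siNT and 218 ± 5.85 in siMNX1, with a log2 fold change of 0.25 that did not pass either (limma, adjusted p = 0.222). Of the 5 tested genes within 250 kb of MNX1, limma called 0, and 1 (MNX1-AS1) had an unadjusted p under 0.05.

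PERCC1, a gene needed for the enteroendocrine cells of the gut, was 18.9-fold higher with MNX1 siRNA. It rose from 44.3 ± 9.25 to 842 ± 59.1 normalized counts (log2 fold change 4.24, SE 0.159, limma, adjusted p = 2.47e-06). SST, which encodes somatostatin, rose from 220 ± 16.6 to 858 ± 24.5 (log2 fold change 1.96, SE 0.085, limma, adjusted p = 3.97e-06), a 3.89-fold difference. HHEX, a transcription factor that maintains somatostatin-producing delta cells, rose from 54.1 ± 10.6 to 484 ± 24.4 (log2 fold change 3.16, limma, adjusted p = 9.62e-06). For each of these 3 genes every siMNX1 library lay above every siNT library. INS, which encodes insulin, had 110540 ± 3758 in siNT and 125390 ± 5655 in siMNX1. Its log2 fold change of 0.18 did not pass the threshold (limma, adjusted p = 0.0656), but it passed with a robust variance model (adjusted p = 0.0314) and after the correction for transcript length and GC content (adjusted p = 0.0149), within a range of 0.0149 to 0.222 over all alternatives. IAPP, which encodes islet amyloid polypeptide, fell from 57.8 ± 16.1 to 15.3 ± 3.75 (log2 fold change -1.84, limma, adjusted p = 0.0123). The IAPP call ended without siNT replicate 1 (adjusted p = 0.0583), without siNT replicate 2 (0.0671) and with both libraries of highest mitochondrial share left out (0.116), and its adjusted p ran from 0.00927 to 0.116 over all alternatives.

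**Figure D1:**
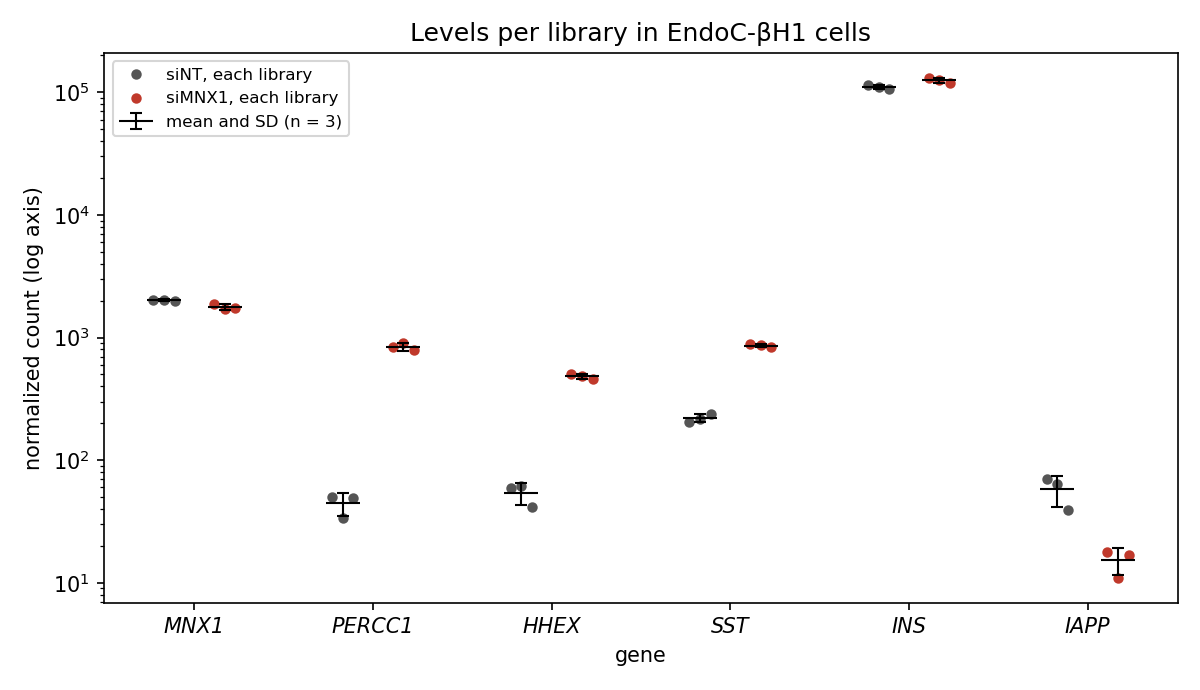
Normalized counts (log axis) of 6 genes in each siNT (grey) and siMNX1 (red) library, where horizontal marks are means and bars are SD (n = 3). PERCC1, HHEX and SST were higher in every siMNX1 library, at means of 842, 484 and 858 against 44.3, 54.1 and 220 in siNT, while MNX1 stood at 1781 against 2020.

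Genes around PERCC1 were then examined. PERCC1 lies on the plus strand of chromosome 16 (1431035 to 1433397, GRCh38). Of its 19 tested neighbours within 250 kb, 3 were higher and 0 were lower by limma, and 5 had an unadjusted p under 0.05. CCDC154 (1434383 to 1444556, minus strand) rose from 2.87 ± 1.08 to 55.4 ± 15.6 (log2 fold change 3.86, limma, adjusted p = 0.000612). ENSG00000279930 (1437154 to 1439315, plus strand), an unnamed transcript inside CCDC154 on the opposite strand, rose from 50.6 ± 15.6 to 1001 ± 94.0 (log2 fold change 4.32, limma, adjusted p = 4.25e-06). CCDC154 and ENSG00000279930 overlap on opposite strands, and since the handling of strand is not given their reads cannot be told apart. BAIAP3 (1333601 to 1349441, plus strand), which encodes a protein of dense-core vesicle trafficking, rose from 156 ± 9.81 to 782 ± 48.2 (log2 fold change 2.32, limma, adjusted p = 2.47e-06). It ends 81.6 kb before PERCC1. In between lie TSR3, GNPTG, UNKL and C16orf91, named after their values were seen, with log2 fold changes of -0.11, 0.11, 0.26 and -0.12. Limma called 0 of these 4 genes, and 0 had an unadjusted p under 0.05.

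**Figure D2:**
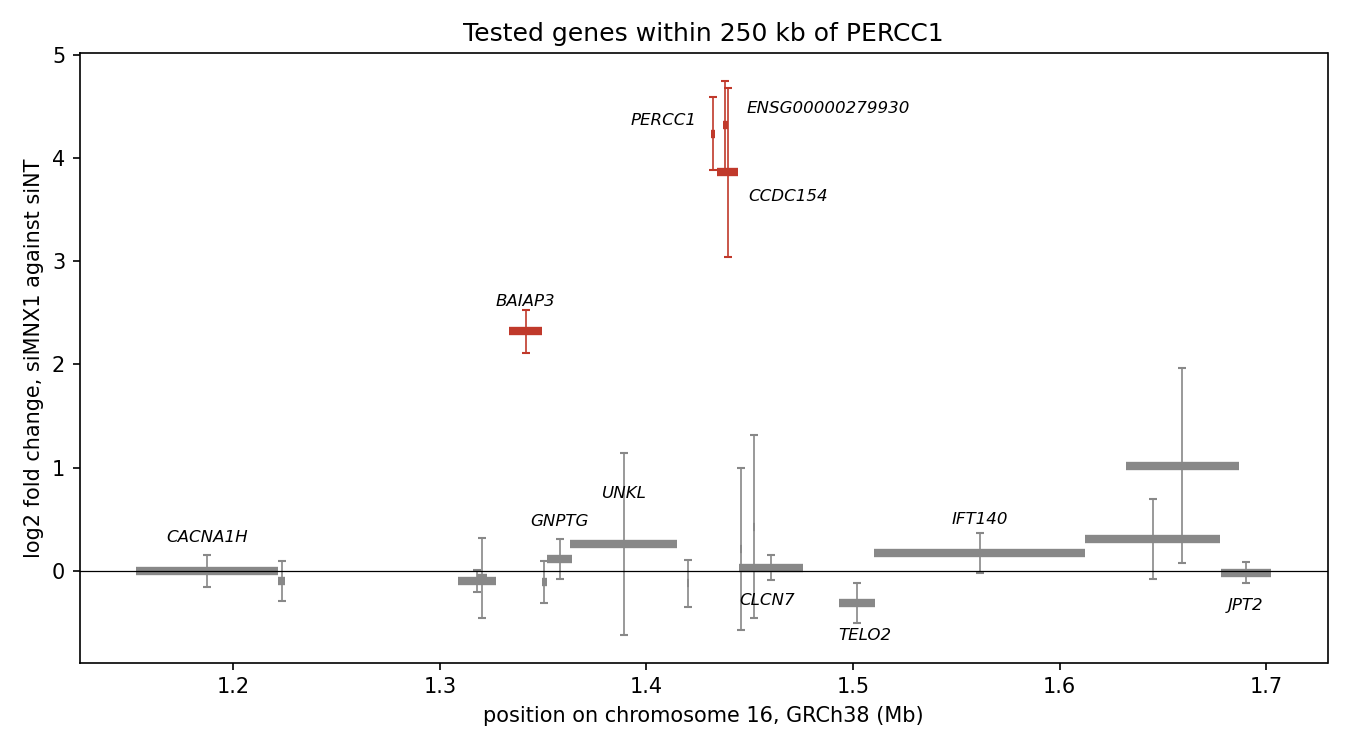
Log2 fold change (vertical axis) of tested genes within 250 kb of PERCC1 by position on chromosome 16 (Mb, GRCh38), where thick lines span each gene, thin bars are 95% intervals, and red marks genes past the threshold. PERCC1, CCDC154, ENSG00000279930 and BAIAP3 lie at 4.24, 3.86, 4.32 and 2.32, and the other genes are grey.

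Across the transcriptome, 335 genes were higher and 223 were lower with MNX1 siRNA out of 16792 tested by limma. At least 2-fold changes were found for 64 of the higher and 23 of the lower genes, 87 in all. Among the higher genes, FN1, which encodes fibronectin, rose from 598 ± 154 to 2578 ± 232 (log2 fold change 2.14, limma, adjusted p = 0.000185). UGT2B7, an enzyme that glucuronidates steroids and drugs, rose from 1641 ± 42.5 to 3830 ± 42.5 (log2 fold change 1.22, limma, adjusted p = 2.47e-06), with the reservation that genes of its family can share reads. OLFML3, C6orf141, TMEM190, ZNF618 and SV2B rose by log2 fold changes of 1.66 to 1.85. Among the lower genes, the noradrenaline transporter SLC6A2 fell from 185 ± 20.5 to 68.4 ± 8.53 (log2 fold change -1.42, limma, adjusted p = 0.00135). GALNT14, CHRNA1, complement C5, CDC42EP2 and the proteoglycan gene GPC3 had log2 fold changes of -1.16, -1.09, -1.05, -1.01 and -0.99 and passed the threshold. The matrix protein gene MFAP4 fell from 2940 ± 62.5 to 1613 ± 120 and SLC45A2 from 4659 ± 281 to 2876 ± 55.4. IGSF1 (-1.34), FBLIM1 (-1.31) and GMPR (-0.99) also passed. The IGSF1 call ended without siNT replicate 2 (adjusted p = 0.088), siNT replicate 3 (0.115), siMNX1 replicate 1 (0.0785) or siMNX1 replicate 3 (0.0617). The FBLIM1 call ended without siNT replicates 1 (0.059), 2 (0.0917) or 3 (0.112) or siMNX1 replicate 1 (0.0649), and the GMPR call without siNT replicate 2 (0.0889), siNT replicate 3 (0.108) or siMNX1 replicate 1 (0.0731).

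The groups did not overlap for 24.0% of all genes, where chance gives 10% for 3 against 3. Counts fell when libraries were left out. Higher and lower genes numbered 190 and 80 without siNT replicate 1, 157 and 65 without siNT replicate 2, 133 and 65 without siNT replicate 3, 164 and 92 without siMNX1 replicate 1, 257 and 179 without siMNX1 replicate 2, and 222 and 121 without siMNX1 replicate 3. Genes changed at least 2-fold numbered 55, 57 and 55 without siNT replicates 1, 2 and 3. With both libraries of highest mitochondrial share left out, 96 genes were higher, 27 were lower and 50 were changed at least 2-fold. That setting also ended calls that had been kept with any single library left out, among them those of SV2B (adjusted p = 0.0532), CDC42EP2 (0.0965), PCSK2 (0.0564), HADH (0.0836), LDHB (0.0815), FFAR4 (0.058) and G6PC2 (0.0965). Log2 fold changes moved little for SV2B (1.66 to 1.71), LDHB (-0.58 to -0.59) and FFAR4 (-0.62 to -0.62), and more for G6PC2 (-0.36 to -0.28). This setting has fewer samples and no other pair of libraries was left out, so the losses cannot be assigned to mitochondrial share.

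**Figure D3:**
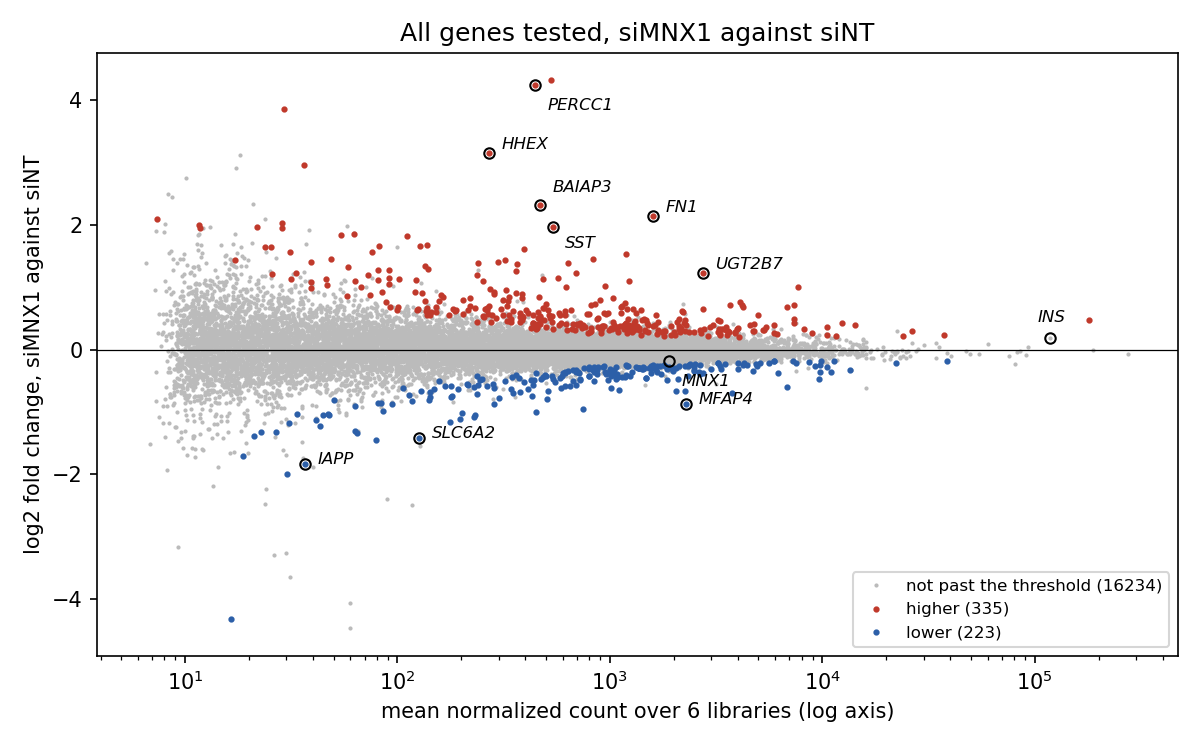
Log2 fold change (vertical axis) against the mean normalized count over 6 libraries (log axis) for all 16792 genes. Red points are the 335 higher and blue points the 223 lower genes, and circles mark named genes, with PERCC1 at 4.24 and MNX1 at -0.18.

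Of the islet cell lists, delta cell markers were split. Of 20 fixed members 12 were measured, of which 3 were higher and 2 lower (4 and 2 adjusted over the list alone). SST, HHEX and CASR, the calcium-sensing receptor gene (6112 ± 87.1 to 8607 ± 656, limma, adjusted p = 0.00183), rose. RBP4, which encodes the retinol carrier, fell from 981 ± 26.8 to 507 ± 54.5 (log2 fold change -0.96, limma, adjusted p = 0.000451), as did FFAR4 (log2 fold change -0.62), named after its values were seen. The list did not stand apart from other genes by camera (adjusted p = 0.173, and adjusted p = 0.674 with an estimated correlation), while fry gave an upward balance (adjusted p = 0.00232).

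Among 21 beta cell transcription factors, 3 were higher and 0 lower (4 and 0 adjusted over the list alone, 6 and 2 at an unadjusted p under 0.05 by limma). Neither camera (adjusted p = 0.354) nor fry (adjusted p = 0.114) called this list as a whole. RFX6, needed for islet development and beta cell function, rose from 2784 ± 14.8 to 4565 ± 81.1 (log2 fold change 0.71, limma, adjusted p = 4.1e-05). MAFA, an activator of the insulin gene, rose by 0.56 and RFX3 by 0.51 on the log2 scale. The MAFA call ended without siNT replicate 2 (adjusted p = 0.0604), siNT replicate 3 (0.0699) or siMNX1 replicate 1 (0.0549), and the RFX3 call without the same libraries (0.0826, 0.0727 and 0.0693). Of 31 beta cell function genes, 6 were higher and 3 lower (10 and 5 adjusted over the list alone). CHGA, which encodes chromogranin A of secretory granules, rose from 150360 ± 2095 to 208160 ± 6547 (log2 fold change 0.47, limma, adjusted p = 0.000267), and the granule protein gene PTPRN and the prohormone convertase gene PCSK2 rose by 0.42 and 0.56. HADH, a fatty acid oxidation enzyme, fell from 15016 ± 467 to 12025 ± 188, beside IAPP and, named after its values were seen, G6PC2 (log2 fold change -0.36). This list's median log2 fold change was 0.06, its mean was -0.0008 and camera pointed up without a call (adjusted p = 0.173).

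Alpha cell markers went both ways, with 2 higher and 2 lower of 12 (2 and 2 adjusted over the list alone). RGS4, a regulator of G protein signalling, rose from 163 ± 14.2 to 431 ± 45.7, and KCTD12 rose by 0.56 on the log2 scale. CRYBA2 fell from 2758 ± 38.5 to 1749 ± 99.5 and GC had a log2 fold change of -0.28, a call that ended without siNT replicate 2 (adjusted p = 0.0513). The list's median was -0.04 and its mean 0.07, camera pointed down and fry up, and neither made a call. Of 12 gamma and epsilon cell markers, 0 were higher and 2 lower (1 and 2 adjusted over the list alone, 1 and 3 unadjusted by limma). They were INPP5F (-0.57) and SERTM1 (-0.66). Neither camera (adjusted p = 0.446) nor fry (adjusted p = 0.126) called the gamma and epsilon list. Left-out libraries gave adjusted p from 0.0255 to 0.102 for INPP5F and from 0.0418 to 0.129 for SERTM1, and ended both calls in 5 of 6 cases, all but siMNX1 replicate 2. Of 13 endocrine progenitor genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, 1 and 1 unadjusted by limma). The median of that list was -0.01, its mean 0.02 and camera pointed up, with no call.

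Among genes of excitability, 4 of 30 ion channel genes were higher and 0 lower (5 and 3 adjusted over the list alone, 6 and 3 unadjusted by limma). Neither camera (adjusted p = 0.28, and 0.674 with an estimated correlation) nor fry (adjusted p = 0.063) called the ion channel list. CACNA2D1, a calcium channel subunit, rose from 9166 ± 120 to 11785 ± 472 (log2 fold change 0.36, limma, adjusted p = 0.00243). HCN4 (0.59), CACNA1A (0.89) and CACNA1D (0.42) also passed. The HCN4 call ended without siNT replicate 3 (adjusted p = 0.0597), the CACNA1A call without siNT replicate 1 (0.0554), siNT replicate 2 (0.0566) or siMNX1 replicate 3 (0.0507), and the CACNA1D call without siNT replicate 2 (0.121), siNT replicate 3 (0.141), siMNX1 replicate 2 (0.0715) or siMNX1 replicate 3 (0.0754). Of 28 exocytosis genes, 2 were higher and 0 lower (8 and 4 adjusted over the list alone, 9 and 6 unadjusted by limma). That list was called neither by camera (adjusted p = 0.486) nor by fry (adjusted p = 0.46). SYT4, a synaptotagmin, rose from 640 ± 43.6 to 1062 ± 76.6. SYT11 (0.34) passed, but its call was kept only when siNT replicate 1 was the library left out, with adjusted p of 0.0292 to 0.124 over the left-out libraries.

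Of 19 measured glycolysis genes, 6 were lower and 0 higher (9 and 1 adjusted over the list alone, 11 and 1 unadjusted by limma), 18 had a log2 fold change below 0, and the median was -0.24. The list stood apart by camera with the preset correlation (adjusted p = 1.1e-07), a call that was lost with an estimated correlation (adjusted p = 0.674), and fry gave an adjusted p of 0.126. LDHB fell from 775 ± 8.48 to 519 ± 49.0 (log2 fold change -0.58, limma, adjusted p = 0.00549), and GPI, ENO2 and ENO1 had log2 fold changes of -0.35, -0.35 and -0.35. GAPDH (-0.19) and, named after its values were seen, TPI1 (-0.25) were the others. Left-out libraries ended the GAPDH call in 6 of 6 cases (adjusted p from 0.079 to 0.146), the ENO1 call in 5 of 6 (all but siMNX1 replicate 1, up to 0.108), the GPI call without siNT replicates 1 (0.0725), 2 (0.0611) or 3 (0.0683) or siMNX1 replicate 1 (0.0595), and the ENO2 call without siNT replicate 2 (0.0917), siNT replicate 3 (0.106) or siMNX1 replicate 1 (0.0672). TMM scaling (adjusted p = 0.0516), equal totals (0.0589), a pseudocount of 5 (0.0542), the stricter filter (0.05) and the length and GC correction (0.0536) also ended the GAPDH call. The TPI1 call ended in 6 of 6 left-out cases (adjusted p from 0.0615 to 0.141) and with equal totals (0.0506). Without siMNX1 replicate 2 the list median was -0.16.

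Cell cycle genes and nuclear oxidative phosphorylation genes had median log2 fold changes of -0.07 and -0.07 over 33 and 31 genes. Camera placed both lower, each with an adjusted p of 0.0207, and both calls were lost with an estimated correlation (adjusted p = 0.674 and adjusted p = 0.709). The cell cycle call also ended without siNT replicate 2 (adjusted p = 0.0973) or siMNX1 replicate 1 (0.109), and the oxidative phosphorylation call without siNT replicate 2 (0.14) or siMNX1 replicate 2 (0.143). Of the cell cycle genes, 1 was lower and 0 higher (4 and 0 adjusted over the list alone, 9 and 1 unadjusted by limma). It was PCNA (12072 ± 399 to 10639 ± 116), whose call ended in 6 of 6 left-out cases (adjusted p from 0.0821 to 0.166). Limma called 0 oxidative phosphorylation genes (0 adjusted over the list alone, 3 lower and 0 higher unadjusted), and ATP5F1B and ATP5F1A had log2 fold changes of -0.12 and -0.05.

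Acinar markers, ductal markers, and mesenchymal, endothelial and immune markers gave 0 calls by limma. The deposited genes held 5 of 22 fixed acinar markers, 9 of 19 ductal markers and 5 of 22 mesenchymal, endothelial and immune markers. They also held 9 of 27 gut and other peptide hormone genes and 7 of 23 motor neuron genes. The missing members could not be assessed, so a lack of calls does not speak for them. Of 5 acinar markers, 0 passed adjusted over the list alone or unadjusted, CPA1 had 591 ± 43.0 and 585 ± 10.4, and the list's median was -0.01 and its mean 0.003. Of 9 ductal markers, 2 were lower adjusted over the list alone, with 2 lower and 1 higher unadjusted, and KRT8 and KRT19 had log2 fold changes of -0.04 and 0.19. Of 5 mesenchymal, endothelial and immune markers, 1 was lower adjusted over the list alone and 2 unadjusted, and CD74 had a log2 fold change of -0.18. For this last list the median was 0.02 while camera pointed down, with no call. Of 9 gut and other peptide hormone genes, 0 passed adjusted over the list alone or unadjusted, and SCT, which encodes secretin, had 1204 ± 70.7 and 1303 ± 15.8. Of 7 motor neuron genes, 1 was lower and 0 higher (1 and 0 adjusted over the list alone, 1 lower and 1 higher unadjusted). It was LMO4 (-0.27). Of 15 genes normally silent in adult beta cells, 1 was higher and 1 lower, the latter again LMO4 (3 and 3 adjusted over the list alone). The name of this list does not describe the cells used here, where siNT means of its members ran from 7.92 to 3780. Left-out libraries ended the LMO4 call in all cases but siMNX1 replicate 2 (adjusted p from 0.0477 to 0.144).

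In the lists for stress and general cell state, 4 lists had 1 gene past the threshold each and the others had 0. Of 26 endoplasmic reticulum stress genes, 1 was higher and 0 lower (3 and 0 adjusted over the list alone, 7 and 3 unadjusted by limma). It was PPP1R15A (0.55). Of 19 interferon response genes, 1 was lower and 0 higher (2 and 1 adjusted over the list alone, 2 and 2 unadjusted), IFI6 (-0.28). Of 23 cholesterol synthesis genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone, 6 and 2 unadjusted). Of 15 housekeeping genes, 1 was lower and 0 higher (1 and 0 adjusted over the list alone, 4 and 2 unadjusted), GAPDH. Left-out libraries gave adjusted p of 0.0182 to 0.0674 for PPP1R15A, which held only without siMNX1 replicates 2 or 3, and of 0.0561 to 0.138 for IFI6, which held in 0 of 6 cases and was also lost after the length and GC correction (0.0574). GAPDH ran from 0.079 to 0.146 and held in 0 of 6 cases. Limma called 0 of 16 p53 and apoptosis genes, 15 mitochondrially encoded genes, 30 ribosomal protein genes, 13 immediate early genes and 11 replication-dependent histone genes, and 0 adjusted over the list alone. At an unadjusted p under 0.05 these lists had 7, 1, 2, 1 and 1 genes, where 3084 of all 16792 genes had such a p. The mixed test of fry, which asks whether a list's own genes change in either direction, passed for 19 of the 26 lists. Among them were endoplasmic reticulum stress (adjusted p = 6.47e-05), interferon response (0.000536), p53 and apoptosis (0.00155), cholesterol synthesis (0.00155) and housekeeping genes (0.0174). For these named lists camera made no call (lowest adjusted p = 0.377, housekeeping genes). Fry's test of movement one way on balance made none either (lowest adjusted p = 0.176, endoplasmic reticulum stress). The mixed test does not compare a list with other genes, so passing it does not set these lists apart. BCL2L1 was the most abundant of the p53 and apoptosis genes, with a log2 fold change of 0.11. The most abundant mitochondrially encoded, ribosomal protein and immediate early genes were MT-CO1 (-0.07), RPS2 (-0.10) and JUND (0.02).

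**Figure D4:**
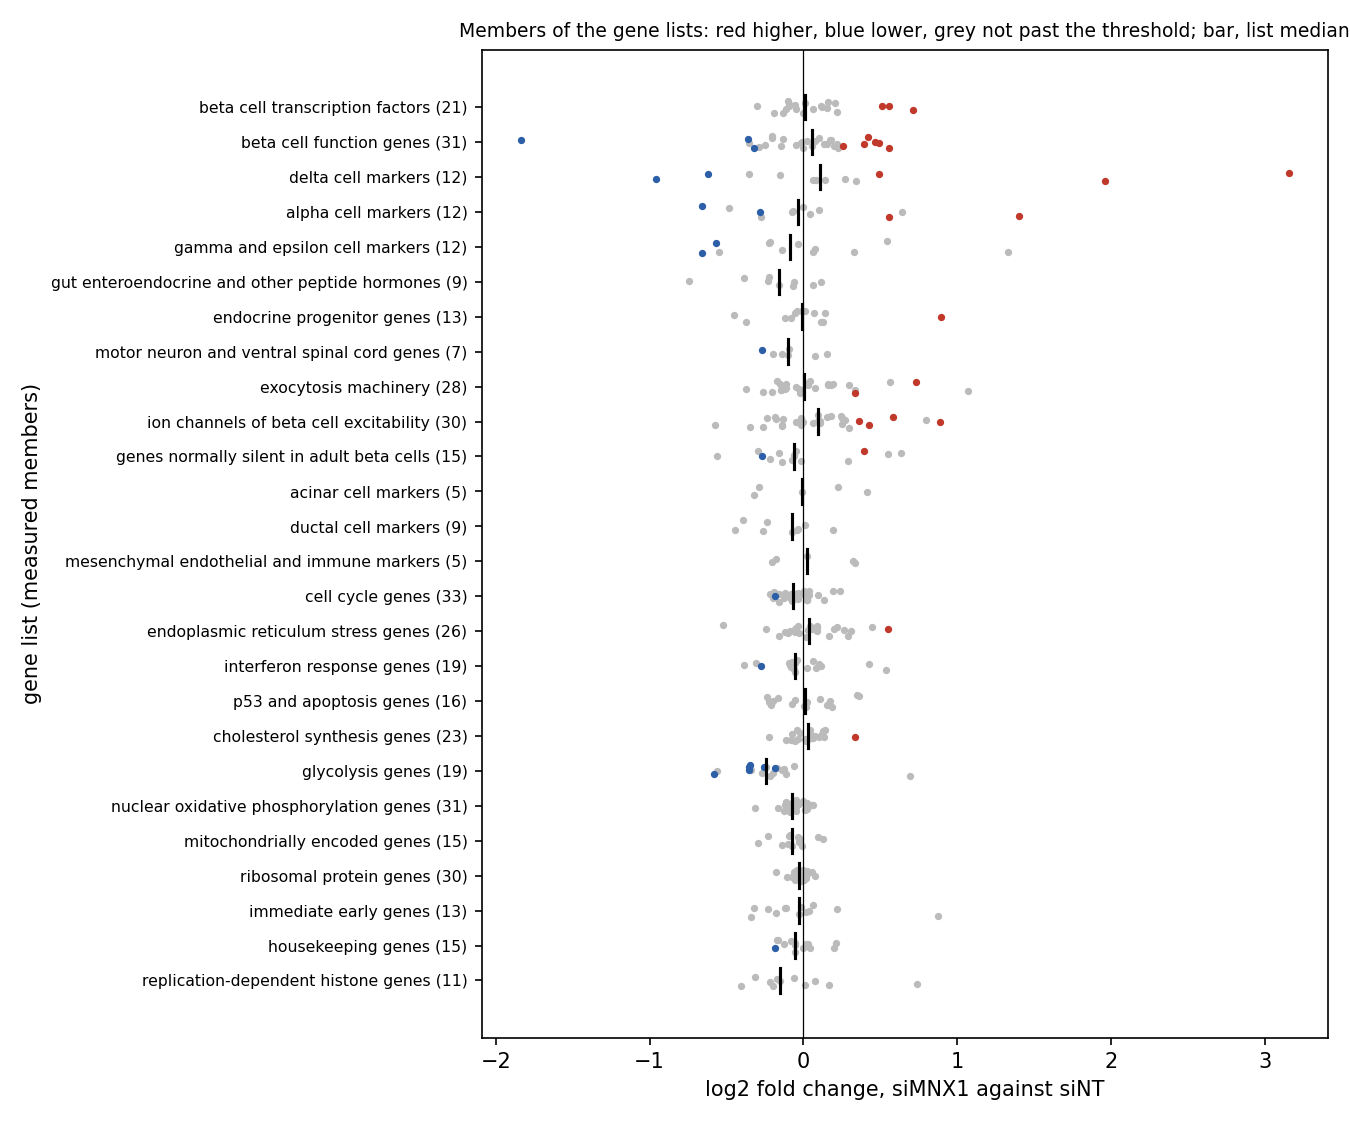
Log2 fold changes (horizontal axis) of the measured members of each of the 26 gene lists, where each point is a gene, red is higher, blue is lower, grey is not past the threshold, and black bars are list medians. The glycolysis list has its median at -0.24, and in the delta cell list HHEX and SST lie at 3.16 and 1.96.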

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

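Scaling by non-mitochondrial totals, the length and GC correction and leaving out both libraries of highest mitochondrial share were chosen after seeing the data. PERCC1 and SST remained past the threshold in the same direction under all 17 alternatives, with log2 fold changes of 4.05 to 4.34 and 1.92 to 2.02. MNX1 stayed lower and short of the threshold, at -0.22 to -0.13. No gene called in the main analysis changed direction under any alternative, and 3 to 4 neighbours of PERCC1 and MNX1 passed. Of the 57 other called genes that the naming rule took or that lie next to PERCC1, 34 kept their calls whichever library was left out. The rule favoured large changes and small p, and a smaller share of all calls held. Without siNT replicate 3 alone, 130 of the 335 higher and 60 of the 223 lower genes kept their calls. Leaving out 1 library gave 133 to 257 higher genes, 65 to 179 lower genes, 55 to 79 genes changed at least 2-fold and 1 to 4 gene lists past the threshold, each from fewer samples. With a replicate block, 162 genes were higher and 75 lower. Same-numbered libraries did not deviate together (correlations of -0.0135, -0.0085 and -0.0377), so the numbers were not taken to pair the samples. With both libraries of highest mitochondrial share left out, again with fewer samples, 96 genes were higher, 27 lower and 50 changed at least 2-fold, and 1 list passed. An estimated inter-gene correlation left 0 lists. A threshold of 1.5-fold in place of 2-fold gave 206 genes, as its construction implies. Other pseudocounts, the stricter filter, other scalings, the robust variance model and the length and GC correction gave 323 to 363 higher and 223 to 266 lower genes. Dropping the filter changed nothing, because it had removed 0 genes. The planned count tests were not run, because whole reads could not be recovered, and TMM factors were computed on the deposited values. The reads behind each value are unknown, which limits statements about genes near the lowest means.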

Other observations

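The genes described first were chosen after seeing the values, and so were the tests of the MNX1 interval, of exchanged libraries, of the PERCC1 ratios, of the genes between BAIAP3 and PERCC1, and of neighbours outside the PERCC1 interval or without like symbols, as well as the length and GC correction and 1 of the 3 other scalings (equal totals of non-mitochondrial genes). Genes higher with MNX1 siRNA were over-represented in 3 of 50 terms of the deposited annotation column, which gives each of 10425 genes 1 term. These were the extracellular region (11 of 133 genes, 3.07 expected, one-sided Fisher's exact test, adjusted p = 0.0126), membrane (38 of 982, adjusted p = 0.02) and G protein-coupled receptor signaling (9 of 113, adjusted p = 0.02). Secreted products among them included SST, FN1, APOA1, IGF2 and both C4 genes, and the receptor group held CASR, PTGER3, PTGER2 and GPBAR1. The higher genes had a median genomic span of 48.78 kb, against 22.5 kb for lower genes and 26.37 kb for genes not called. These term tests were not adjusted for genomic span, and the length and GC correction used transcript length. Fisher's test also treats genes as independent, although C4A and C4B share reads and count separately here. The IGF2 call (limma, adjusted p = 0.0392) ended in 6 of 6 left-out cases (0.0679 to 0.124). The PTGER2 call (limma, adjusted p = 0.0398, 9.02 ± 5.76 to 34.6 ± 6.84) was kept only without siNT replicate 2 (0.0259, otherwise 0.0831 to 0.119). With both libraries of highest mitochondrial share left out, the calls of IGF2 (adjusted p = 0.187), PTGER2 (0.0922) and GPBAR1 (0.0702) ended. Genes lower with MNX1 siRNA gave 0 terms by the same test, with 3 at an unadjusted p under 0.05. G protein-coupled receptor signaling was among these 3 as well (5 of 113 genes, 1.92 expected, one-sided Fisher's exact test, unadjusted p = 0.0432, adjusted p = 0.718). Its lower genes included PTGDR2 and FFAR4.

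Several gene families had members past the threshold (limma). C4A rose from 784 ± 109 to 1681 ± 180 and C4B from 747 ± 35.7 to 1328 ± 90.0, although these near-identical genes share reads, while C5 fell from 313 ± 22.6 to 152 ± 24.4. The prostaglandin E2 receptor gene PTGER3 rose from 194 ± 17.6 to 597 ± 64.7 (log2 fold change 1.62) and the prostaglandin D2 receptor gene PTGDR2 fell from 2433 ± 81.1 to 1746 ± 36.5 (log2 fold change -0.48). The GABA receptor subunit gene GABRA2 rose from 614 ± 74.1 to 1780 ± 73.8 (log2 fold change 1.54), and the adenylyl cyclase gene ADCY2 from 417 ± 72.0 to 968 ± 13.0 (log2 fold change 1.23). CYP4F3 and CYP4F12, relatives that may share reads, rose by 1.01 and 1.44, among 4 higher and 0 lower of 7 measured members of their family, where the correction for transcript length and GC content left 4 higher as well. The other members past the threshold were CYP4F2 (2.04), whose call ended without siNT replicate 1 (adjusted p = 0.0506), siNT replicate 3 (0.0628), siMNX1 replicate 1 (0.0637) or siMNX1 replicate 3 (0.0501), and CYP4F24P (1.65), whose call ended in 6 of 6 left-out cases (0.0573 to 0.0965). Both calls also ended with both libraries of highest mitochondrial share left out (0.109 and 0.158). Of 11 alpha and beta tubulin genes, 4 were lower and 1 higher under the main analysis. The counts were the same under each of 3 other scalings, whose factors (0.993 to 1.01) hardly alter the values. TUBB6 (-0.43) kept its call whichever single library was left out, and TUBB4B (-0.26) lost its call without siNT replicate 3 (adjusted p = 0.0619). TUBB (-0.21) kept its call only without siNT replicate 1 or siMNX1 replicate 2 (otherwise 0.0585 to 0.104), and TUBB3 (-0.24) and the higher TUBB1 (0.42) only without siMNX1 replicate 2 (otherwise 0.0577 to 0.115 and 0.0522 to 0.122). With both libraries of highest mitochondrial share left out, the calls of TUBB6 (adjusted p = 0.0952), TUBB4B (0.0836), TUBB (0.176), TUBB3 (0.139) and TUBB1 (0.136) all ended.

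MNX1 RNA was little lower while PERCC1, HHEX and SST were several-fold higher. An imprecise MNX1 measurement is argued against by the lower end of its 95% interval, -0.3071, which is far from the -1 of a halved level. An exchange of 1 or 2 libraries between the groups is argued against too, since another of the 10 splits of the libraries would then call more genes than the labelled one, which called 558, and the highest of the others was 3. Whether library scaling hides a larger fall stays open, since the most negative log2 fold change over 3 other scalings was -0.1904, but the values had been normalized before and the factors, from 0.993 to 1.01, lay too close to 1 to bring MNX1 to -0.5. Recovery of the transcript before harvest, an action of the siRNA on translation, and effects on genes other than MNX1 stay open, as hypotheses that these data may fit equally well and that were not tested.

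PERCC1 and 3 of its 19 tested neighbours were higher. ENSG00000279930 stood to PERCC1 at a mean ratio of 1.1881 ± 0.0694 in siMNX1 and 1.1653 ± 0.3528 in siNT libraries. CCDC154 stood at 0.0651 ± 0.0138 and 0.0653 ± 0.02. Reads of 1 transcript counted under several genes would give like ratios, though equal control of separate transcripts would give equal ratios too. The siNT ratios ran from 0.7586 to 1.3888 and from 0.0442 to 0.0839, and CCDC154 had only 2.87 ± 1.08 in siNT. With so wide a spread, the overlap of the groups decides little. A rise of all genes from BAIAP3 to PERCC1 is argued against by the median log2 fold change of 0.0027 in the 4 genes between, while a transcript running from one to the other stays open, since only 1 of the 4, GNPTG (0.11), lies on their strand and the handling of strand is not given. Across the genome 13 adjacent pairs of tested genes were both higher, against 5.16 on average in 10000 shuffles of the calls (one-sided permutation p = 0.0021), and 12 against 5.18 outside the PERCC1 interval (p = 0.0069). Without neighbours whose symbols share their first 4 characters, such as the CYP4F genes, there were 9 pairs against 5.04 (one-sided permutation p = 0.0666), and 8 against 5.02 when the PERCC1 interval was left out as well (p = 0.135), so whether neighbours changed together in general stays open.

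Of 19 glycolysis genes, 6 were lower and 18 had a log2 fold change below 0, and the camera call of the list was lost with an estimated correlation (adjusted p = 0.674) and not made by fry (adjusted p = 0.126). A trend with transcript length and GC content is argued against, since the list median was still -0.2113 after the correction, against -0.2435 before. A negative median set by 1 library is argued against by the highest median with a library left out, -0.1575, found without siMNX1 replicate 2. Shared variation among the genes of this list may still account for the camera call.

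The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes siNT and siMNX1 libraries. A difference between siNT and siMNX1 then widens the spread within the mixed groups and lowers their counts of called genes. Such splits therefore do not show the counts to be had from samples without a difference. The real split gave 335 higher genes (highest other 2), 223 lower genes (highest other 1) and 87 genes changed at least 2-fold (highest other 1), and in each case 1 of the 10 splits gave as many. For gene lists, 4 of the 10 splits gave as many as the 3 of the real one (highest other 5).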
